A study of Mus musculus with 76 samples.

How the data were processed

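RNA was measured in whole-tissue libraries of brain, liver, ovary and testis from house mice that carried a t haplotype or not, in 12 groups of tissue, sex and genotype (76 libraries, 30 animals). Per the labels' protocols, RNA of gonads and liver was taken up with Trizol and a column kit with DNase treatment, RNA of brain with phenol and chloroform, and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, reads were aligned to GRCm38 with STAR 2.5.1b and counted per gene with featureCounts. The deposited values are integer read counts per gene, per the file headers, with totals that differ between libraries. The strand setting of the counting and the annotation release are not given in the sources used here.

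Each file held 25567 gene identifiers, of which 25472 were found in GENCODE M21 and the other 95 (0.031% to 0.133% of the counts of a library) had no position. The t region was taken as chromosome 17 from its start to 40 Mb and held 689 genes of the files. Groups and sibling pairs came from the labels, in which a sibling tag marks each pair. As a check of the pairing, the deviations of siblings from their group means correlated at 0.245 to 0.386 in testis, 0.197 to 0.461 in male liver and 0.22 to 0.685 in female brain. The range was 0.0145 to 0.538 in male brain, 0.0841 to 0.353 in female liver and -0.211 to 0.359 in ovary. The pair was kept as a block in every comparison because the labels name the siblings. Male liver pair 3, whose titles and genotype labels conflict, was kept with its genotype labels. No library was left out.

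For each of the 6 comparisons, genes were kept by filterByExpr with a minimum count of 10, libraries were scaled with TMM factors, and +/t was tested against +/+ with the edgeR 4.0.16 quasi-likelihood test with the sibling pair as a block, in R 4.3.3. For 3 further tests of a difference between the sexes, the libraries of a tissue (or of the gonads) were fitted together with pair blocks and a term for genotype by sex. Some male and female pairs came from the same litter, which had no term of its own in these fits. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of fold changes are the absolute log2 fold change before shrinkage over the square root of the F statistic of the test. The fold changes shown hold the shrinkage toward 0 that edgeR applies, which matters most at low counts. CPM values are means with SD over libraries. DESeq2 1.42.0 served as a second tool. Gene lists written from general knowledge were tested with camera of limma 3.58.1 at a fixed correlation of 0.01 between genes, and again with the correlation estimated; members were also adjusted over the list alone. Calls inside and outside the t region were compared with Fisher's exact test. Overlaps of calls were set against the number expected of independent lists. Transcripts of 90 named genes were compared with all transcripts with blastn 2.17.0 (matches of at least 100 bases at 90% identity), and overlaps with other genes were taken from the annotation.

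Named genes were, among called genes with a mean log2 CPM of at least 1 and the same sign in every pair, the 5 highest and 5 lowest fold changes inside and outside the t region. Added were up to 4 called members of each list, and the genes of a distorter and responder list whether called or not. Up to 8 genes called in the most comparisons and up to 3 genes of each test of a sex difference were added too. The rule, the design, the lists and most alternatives were fixed before the data were examined.

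The alternatives were DESeq2, relative log expression factors, no filter on low counts, a minimum count of 50, no pair block and each pair left out in turn. Others were boundaries of the t region at 35 and 45 Mb, the genotype labels of male liver pair 3 exchanged, and, for lists, an estimated correlation, no block, and no t region genes. After the data were seen, 2 were added: the counts of the 7 even-count libraries halved, and the pairs with such a library left out. Other splits of the libraries into groups of the same sizes were fitted in the same way, 100 for each comparison (60 for the gonads, real split included), as were all exchanges of genotype within pairs.

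The fits with edgeR and DESeq2 were tested on simulated data with 200 changed genes, drawn from the means and sizes of the real libraries. The camera test was run on simulated data with a changed list in each comparison. The other steps were not tested in this way. For changes of 1.5-fold, edgeR called 88.0% of them in male brain, 84.0% in female brain, 64.6% in male liver, 72.0% in female liver, 50.0% in ovary and 78.0% in testis. For sex differences of that size it called 72.0% in brain, 34.0% in liver and 16.0% in gonads. Library totals were 8.27 to 45.2 M counts (M, mega). Biological coefficients of variation were 7.17% and 8.45% in male and female brain, 14.4% and 15.0% in male and female liver, 19.6% in ovary and 6.48% in testis. How far depth, variation and the number of pairs each set the shares called was not tested.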

Results

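Read counts of 25567 genes were deposited for 76 RNA-seq libraries of brain, liver, ovary and testis from lab-reared descendants of wild-caught house mice (Mus musculus domesticus). The animals formed 15 same-sex sibling pairs from 10 litters. In each pair 1 animal carried a t haplotype (+/t) and its sibling did not (+/+). A t haplotype is a variant form of the proximal part of chromosome 17 that is held together by inversions and is passed on by +/t males to most of their offspring. Brain was sampled from 5 male and 7 female pairs, liver from 7 male and 6 female pairs, ovary from 7 pairs and testis from 6. The comparisons ask which transcripts differ between +/t and +/+ siblings in each tissue and sex, and whether the difference depends on sex.

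Library totals ran from 17 to 45.2 M counts (M, mega) in brain, from 8.27 to 21.2 M in liver, from 9.34 to 23.9 M in ovary and from 11.4 to 28.4 M in testis. In 7 libraries, 59.3% to 68.1% of the gene counts from 20 to below 500 were even numbers, against 48.7% to 51.2% in the other 69. These even-count libraries were brain male +/+ of pair 3, brain female +/+ of pair 4 and brain female +/t of pair 6. The others were liver male +/t of pair 4, ovary +/t of pair 5, and testis +/t of pairs 2 and 3. Ddx3y, a gene of the Y chromosome, stood at 12.4 to 100 CPM (counts per M) in the 36 male libraries and at 0.24 CPM or less in the 40 female libraries. The titles of male liver pair 3 carry animal numbers to which the brain and testis labels give the other genotype. With its genotype labels kept, 65 of the 89 t region genes called in other comparisons (73.0%, 95% exact binomial interval 62.6% to 81.9%, over genes that are not independent) differed in that pair in the direction seen elsewhere. The other male liver pairs gave 69.7% to 77.5%. Pair 3 thus ran the same way as the others, which argues against exchanged genotype labels in its liver libraries.

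Znrd1, which encodes a subunit of RNA polymerase I, was higher in +/t siblings in all 6 comparisons, from 0.79 ± 0.09 (log2 fold change ± SE) in male brain to 1.48 ± 0.09 in female liver. Jmjd8, a jumonji domain gene, was lower in all 6, from -0.60 ± 0.06 in male brain to -0.79 ± 0.06 in male liver. Rsph3a, which encodes a radial spoke protein of cilia and flagella, rose by 1.89 to 3.07 in brain, liver and ovary. In testis its change of 1.35 ± 0.22 had an edgeR adjusted p of 0.0685. Amdhd2, an enzyme gene of amino sugar breakdown, fell in 5 comparisons, with values of -0.43 to -0.79. In ovary it stood at -0.62 ± 0.12 (edgeR adjusted p = 0.221). Tulp4, of the tubby family, fell in 5 comparisons, with values of -0.25 to -0.56. It stood at -0.24 ± 0.07 in male liver (edgeR adjusted p = 0.663). Rnpepl1, an aminopeptidase-like gene on chromosome 1, rose in 5 comparisons, from 0.35 ± 0.04 in testis to 1.44 ± 0.07 in female brain. In female liver it was higher in 6 of 6 pairs by 0.37 ± 0.07 (edgeR adjusted p = 0.106).

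In GRCm38 coordinates, Znrd1 (ENSMUSG00000036315) lies at 36954356 to 36958559 of chromosome 17 and Jmjd8 (ENSMUSG00000025736) at 25828867 to 25831843. Rsph3a (ENSMUSG00000073471) lies at 7945614 to 7979824, Amdhd2 (ENSMUSG00000036820) at 24155833 to 24163766 and Tulp4 (ENSMUSG00000034377) at 6106437 to 6251128. Rnpepl1 (ENSMUSG00000026269) lies at 92910783 to 92924384 of chromosome 1. Each is a protein-coding gene, and a count covers the gene as a whole. Of the 287 genes called in any comparison, 42 were called in 2 or more, each with a single sign, and 39 of these 42 lay in the t region, taken as chromosome 17 from its start to 40 Mb. The 3 others were Rnpepl1, Hmga1b and Gm12355, the latter 2 on chromosome 11. Counts of some of these genes are uncertain. A transcript of Rsph3a matches Rsph3b at 99.4% identity. Hmga1b matches Hmga1 of the t region at 99.8% over 1602 bases, and Gm12355 matches Srsf3 of the t region at 98.3%. Tagap1 matches Tagap at 99% over 2152 bases and Acat2 matches Acat3 at 97.7%. Tulp4, Rps6ka2, Gsta2, Rpl10a, Rps2, Rps18, Cyp2a5, Prr18, Fkbp5, Zfp994 and H2-Bl, named here or below, have matches at 97% or more. Nme3, named below, shares 763 bases with Mrps34 on the same strand. Jmjd8 overlaps Stub1 on the opposite strand, with the strand setting of the counting not given in the sources used here.

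**Figure D1:**
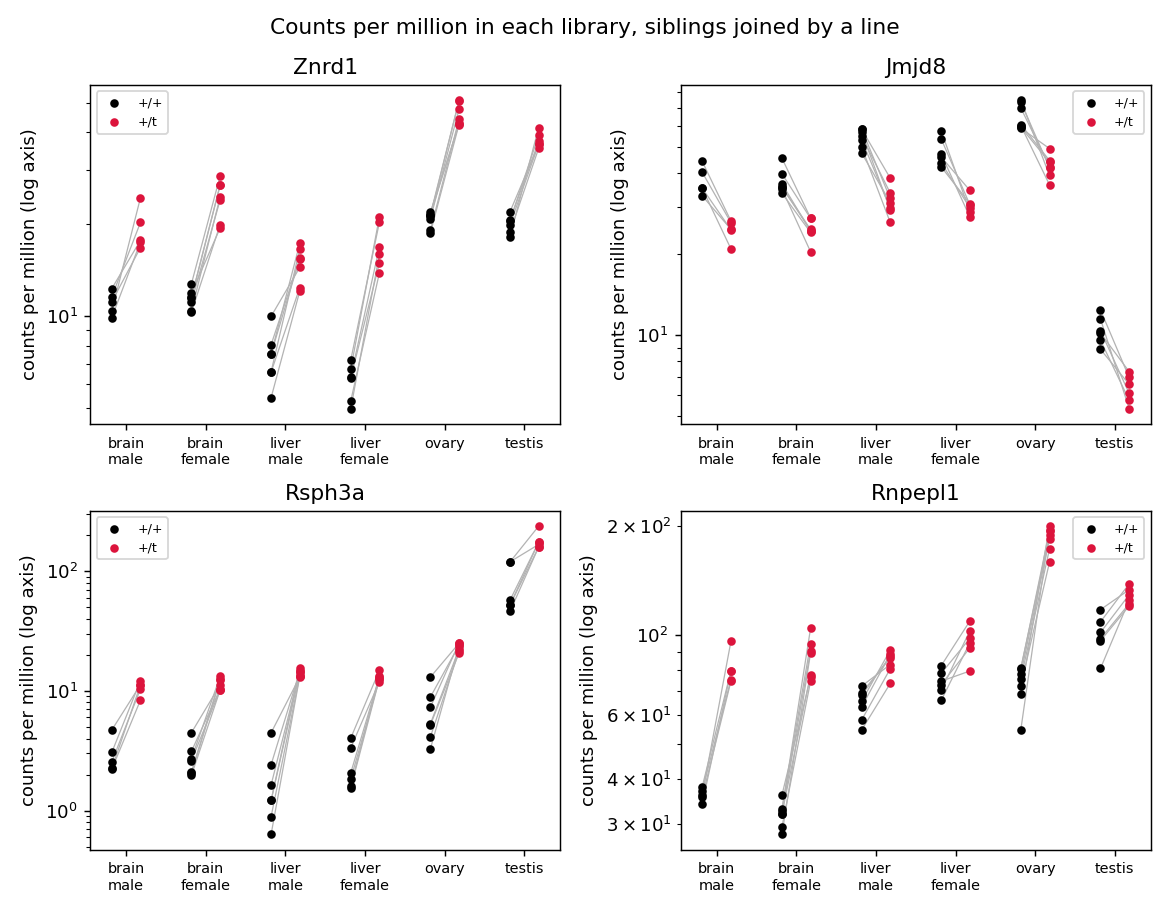
CPM values (log axis) of Znrd1, Jmjd8, Rsph3a and Rnpepl1 in each library, by tissue and sex, with +/+ in black, +/t in red and siblings joined by a line. The line of Rnpepl1 runs upward in all 38 tissue samples of the 15 sibling pairs.

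**Figure D2:**
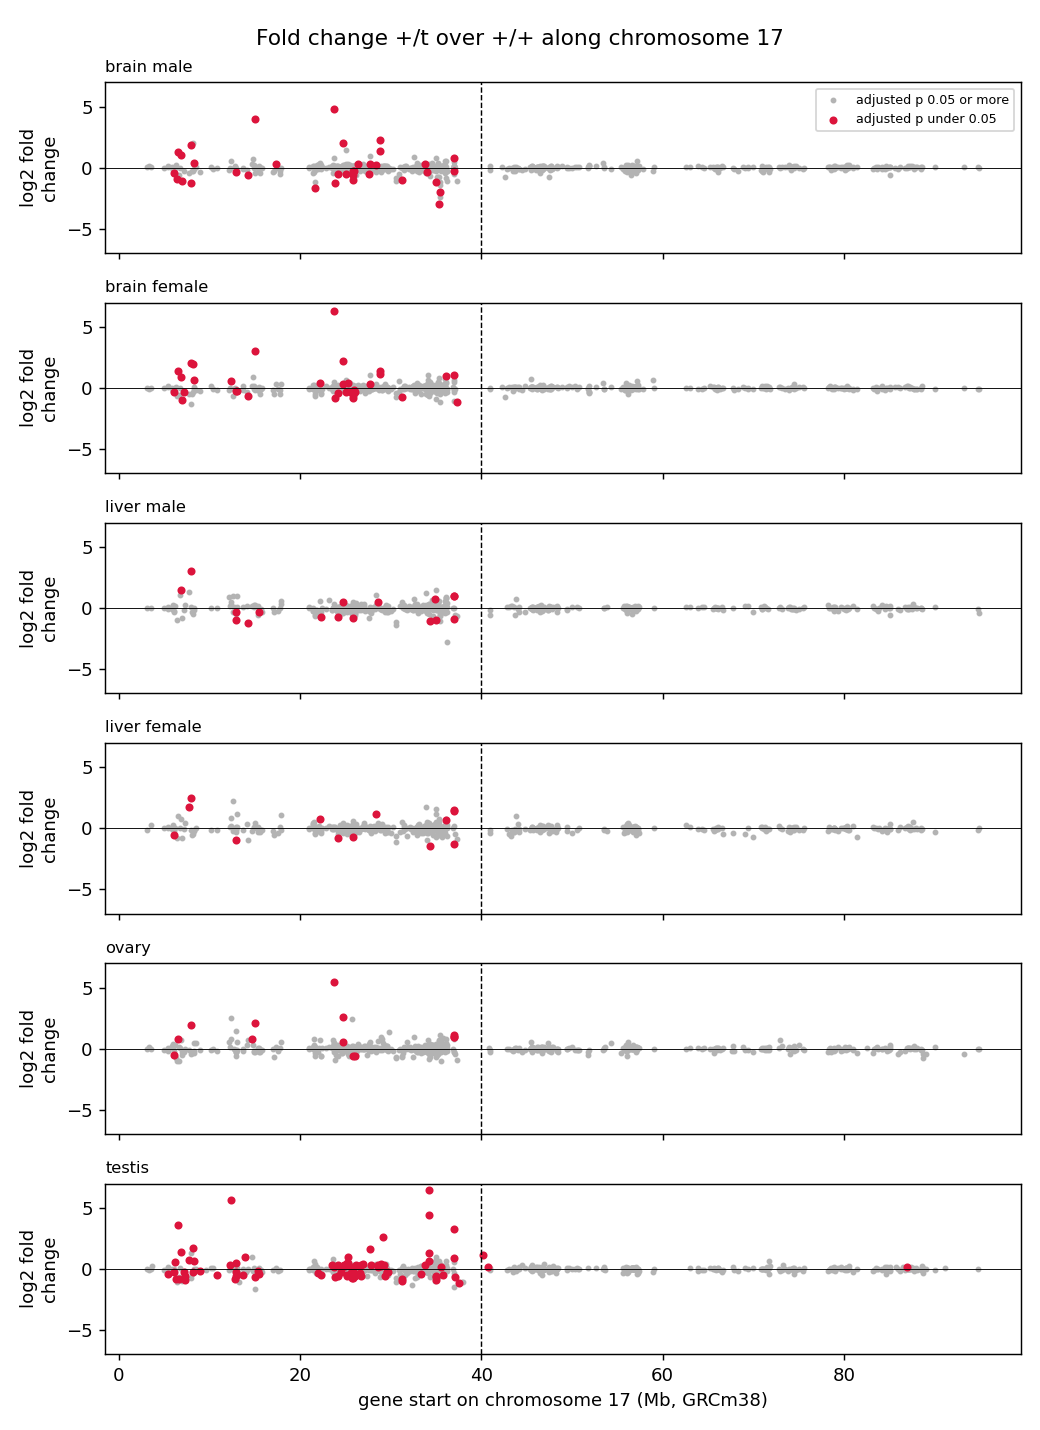
Log2 fold change of +/t over +/+ against gene start on chromosome 17 (Mb, GRCm38), with a panel for each comparison; red points are genes with an adjusted p under 0.05 and the dashed line marks 40 Mb. Red points in both directions lie left of the line, and 3 testis genes lie to its right.

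In male brain, the highest fold changes among called t region genes with a mean log2 CPM of at least 1 began with Rsph3a (1.89 ± 0.14; 2.96 ± 1.04 CPM in +/+ and 10.7 ± 1.44 in +/t, SD, n = 5). Then came Dynlt1c, a cytoplasmic dynein light chain gene (1.29 ± 0.17), and Rsph3b (1.06 ± 0.17). Znrd1 rose by 0.79 ± 0.09 and Prr18 by 0.42 ± 0.06. The lowest was that of H2-Q1, an MHC class I gene (-3.02 ± 0.28; 7.59 ± 3.53 CPM in +/+ and 0.892 ± 0.269 in +/t). Next were the serine protease gene Prss41 (-1.27 ± 0.17), the GTPase-activating genes Tagap (-1.26 ± 0.16) and Tagap1 (-1.12 ± 0.12), and the radial spoke gene Rsph1 (-1.03 ± 0.07). Outside the t region, Rnpepl1 (1.15 ± 0.06), Hmga1b (1.04 ± 0.17) and Gm12355 (2.86 ± 0.26) rose. The sterol transporter gene Npc1l1 fell (-1.05 ± 0.19). Gm12355, under a mean log2 CPM of 1, was chosen after its values were seen.

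Of 21 t complex named genes tested in male brain, 4 rose and 2 fell (4 and 9 adjusted over the list alone). Dynlt1b (-0.92 ± 0.14) and Acat2 (-0.40 ± 0.06) were those that fell. Among 4 tested genes known as t haplotype distorters or responders, Tagap1 fell, while Fgd2 (0.10 ± 0.14), Nme3 (0.18 ± 0.07) and Tiam2 (0.13 ± 0.05) did not pass the test. Adjusted over this list alone, 2 rose and 1 fell. Of 14 MHC class I genes, all in the t region, 2 fell (adjusted over the list alone, 2 rose and 6 fell). The set was lower in +/t with camera (adjusted p = 0.00953; adjusted p = 0.466 with an estimated correlation). Of 25 ribosomal protein genes, Rpl10a rose (0.24 ± 0.04) and Rps18 fell (-0.38 ± 0.06), both of them t region genes, and 2 rose and 1 fell adjusted over the list alone. The set was higher with camera (adjusted p = 0.0011; adjusted p = 0.466 with an estimated correlation). Of 14 oligodendrocyte markers, the myelin gene Mog, itself in the t region, fell (-0.30 ± 0.05), also adjusted over the list alone. The set was lower with camera (adjusted p = 0.0192; adjusted p = 0.466 with an estimated correlation). Macrophage (median 0.073), astrocyte (median 0.085) and striatum markers (median 0.11) were higher as sets with camera (adjusted p = 0.0445, 0.0445 and 0.00229). Each had an adjusted p = 0.466 with an estimated correlation.

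In all, 40 of 15146 genes were called in male brain (18 higher and 22 lower in +/t; edgeR with Benjamini-Hochberg adjustment). They were 36 of the 440 t region genes (8.18%) and 4 of the 14706 others (Fisher's exact test, two-sided, p = 9.28e-52, over genes that are not independent). Without the sibling pair as a block 19 genes were called. Rsph3b, Prr18, Prss41, Tagap, Tagap1, Npc1l1, Dynlt1b, Acat2, Rps18, Rpl10a, Mog, Tulp4 and Amdhd2 did not pass then (edgeR adjusted p = 0.0527 to 0.998), nor did the macrophage, astrocyte and oligodendrocyte sets (camera adjusted p = 0.0949 each). Outside the t region DESeq2 called 9 genes, and 2 were left without pair 3, which holds an even-count library.

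In female brain, Rnf151, a RING finger gene known from testis, had the highest fold change of the called t region genes with a mean log2 CPM of at least 1 (2.20 ± 0.15; 0.833 ± 0.196 CPM in +/+ and 3.81 ± 0.629 in +/t, SD, n = 7). It was followed by Rsph3a (2.08 ± 0.14), Znrd1 (1.09 ± 0.07), the MHC class I gene H2-T10 (0.96 ± 0.14) and Rsph3b (0.91 ± 0.11). Tagap1 (-0.98 ± 0.11), Wdr90 (-0.86 ± 0.10), Prss41 (-0.82 ± 0.14), Rsph1 (-0.72 ± 0.09) and Smoc2, a matrix protein gene (-0.64 ± 0.08), were the lowest of them. Rnpepl1 (1.44 ± 0.07), Hmga1b (0.91 ± 0.15) and Gm12355 (2.76 ± 0.34, chosen after its values were seen) rose outside the region.

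Of 21 t complex named genes in female brain, 4 rose and 3 fell (5 and 10 adjusted over the list alone), among them Dynlt1c (1.42 ± 0.16), the kinase gene Rps6ka2 (-0.30 ± 0.05) and Acat2 (-0.27 ± 0.04). Tagap1 fell among the 4 tested distorter and responder genes, and Fgd2 (0.34 ± 0.11), Nme3 (0.12 ± 0.07) and Tiam2 (-0.10 ± 0.06) did not pass (1 rose and 1 fell adjusted over the list alone). Of 15 MHC class I genes, H2-T10 rose and H2-M3 fell (4 and 2 adjusted over the list alone). The tested genes of both MHC lists lay wholly in the t region in each comparison. The set test called ribosomal proteins, macrophage, astrocyte and oligodendrocyte markers and mitochondrially encoded genes higher (camera adjusted p = 9.09e-05, 0.000901, 0.000901, 0.00129 and 0.00129) and choroid plexus markers lower (0.0124). Each had an adjusted p = 0.731 with an estimated correlation. Of their members, the ribosomal protein gene Rps2 of the t region rose (0.34 ± 0.06). Oligodendrocyte markers had medians of opposite sign in the brains of the sexes, -0.056 in males and 0.076 in females, a difference that was not tested for the list.

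Female brain gave 37 calls among 15116 genes (20 higher and 17 lower; edgeR). They were 34 of the 438 t region genes (7.76%) and 3 of the 14678 others (Fisher's exact test, two-sided, p = 1.02e-49). Without the pair block 21 genes were called and Smoc2, Rps6ka2, Acat2, Tulp4 and Amdhd2 (edgeR adjusted p = 0.163 to 1) and the choroid plexus set (camera adjusted p = 0.0553) did not pass. DESeq2 called 8 genes outside the t region. By edgeR, 24, 23 and 23 genes were called without pair 4, 6 or 8, and 12 without both pairs that hold an even-count library (4 and 6). The t region calls of the sexes overlapped. There, 11 genes rose in both (0.585 expected of independent lists; Fisher's exact test, adjusted p = 4.03e-13) and 12 fell in both (0.819 expected; adjusted p = 5.85e-13). None went opposite ways.

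The difference between the sexes was tested itself in the 24 brain libraries. No gene was called by edgeR among 15624 (815 had an unadjusted p under 0.05), and DESeq2 called 1. The smallest p-values belonged to Cyp2a5, Ugt2a2 and Bpifa1, genes known from nasal epithelium, with male minus female differences of -5.96 ± 0.88, -6.96 ± 1.18 and -9.30 ± 1.69 (edgeR adjusted p = 0.249, 0.544 and 0.848).

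In male liver, Rsph3a was the highest of the called t region genes (3.07 ± 0.30; 1.78 ± 1.31 CPM in +/+ and 14.1 ± 0.878 in +/t, SD, n = 7). It was followed by Rsph3b (1.52 ± 0.23), Znrd1 (1.01 ± 0.10), its neighbour Znrd1as (1.0 ± 0.10) and the lysosomal sialidase gene Neu1 (0.75 ± 0.09). The lowest were Smoc2 (-1.22 ± 0.20), the MHC class II gene H2-Eb1 (-1.02 ± 0.16) and Acat3, an acetyl-CoA acetyltransferase gene (-0.98 ± 0.08; 279 ± 22.2 CPM in +/+ and 143 ± 25.2 in +/t). Next were the meiotic recombination gene Msh5 (-0.96 ± 0.16) and Rnf39 (-0.87 ± 0.14). Rnpepl1 rose (0.39 ± 0.05) and the glutathione transferase gene Gsta2 fell (-0.53 ± 0.09) outside the region. Of 25 ribosomal protein genes Rps2, in the t region, rose (0.53 ± 0.07; 2 rises adjusted over the list alone).

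Of 15 t complex named genes in male liver, 2 rose and 1 fell (5 and 5 adjusted over the list alone). Tagap1 (-0.82 ± 0.15, edgeR adjusted p = 0.078, lower in 7 of 7 pairs), Fgd2 (0.10 ± 0.16) and Nme3 (0.039 ± 0.07) did not pass (1 fell adjusted over the list alone). H2-Eb1 was the called gene among 12 of MHC class II and antigen processing (2 rose and 1 fell adjusted over the list alone). Endothelial markers (median 0.12) and male-biased liver genes (median 0.069) were higher as sets with camera (adjusted p = 0.0034 and 0.0408), with adjusted p = 0.747 and 0.989 with an estimated correlation. Major urinary proteins (median -0.23), carriers of pheromones in urine, and ribosomal proteins (median -0.066) were lower (camera adjusted p = 0.000177 and 0.0099), with adjusted p = 0.747 and 0.989 with an estimated correlation.

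Male liver gave 19 calls among 11938 genes (8 higher and 11 lower; edgeR). They were 17 of the 369 t region genes (4.61%) and 2 of the 11569 others (Fisher's exact test, two-sided, p = 2.41e-24). With any single pair left out 6 to 12 genes were called, 8 of them without pair 4, which holds an even-count library. DESeq2 called 52 (13 outside the t region). Exchanging the genotype labels of pair 3, which its t region genes argue against, left 0 calls by edgeR in place of 19. Without the pair block 1 gene was called outside the t region. Rsph3b, H2-Eb1, Rnf39, Gsta2 and Rps2 (edgeR adjusted p = 0.0913 to 1) and the male-biased set (camera adjusted p = 0.0961) did not pass.

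In female liver, Rsph3a again led the rises among called t region genes with a mean log2 CPM of at least 1 (2.47 ± 0.18; 2.40 ± 1.03 CPM in +/+ and 13.1 ± 1.0 in +/t, SD, n = 6). Znrd1 (1.48 ± 0.09), Znrd1as (1.42 ± 0.09), Fkbp5, a glucocorticoid-responsive co-chaperone gene (1.17 ± 0.13), and the zinc finger gene Zfp994 (0.76 ± 0.11) came next among called genes with a mean log2 CPM of at least 1. H2-Eb1 (-1.44 ± 0.12), Rnf39 (-1.26 ± 0.14), Acat3 (-0.94 ± 0.08; 303 ± 24.2 CPM in +/+ and 158 ± 16.3 in +/t), Amdhd2 (-0.79 ± 0.09) and Jmjd8 (-0.67 ± 0.08) were the lowest of these genes. The MHC class I gene H2-Bl rose by 0.66 ± 0.10.

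Of 16 t complex named genes in female liver, Rsph3a rose and Acat3 fell (5 and 4 adjusted over the list alone). Of 15 MHC class I genes, 1 rose (4 rose and 6 fell adjusted over the list alone). Tagap1 (-0.77 ± 0.17, edgeR adjusted p = 0.230, lower in 6 of 6 pairs), Fgd2 (-0.19 ± 0.23) and Nme3 (0.061 ± 0.09) did not pass (1 fell adjusted over the list alone). Endothelial markers (median -0.23), macrophage markers (median -0.13) and immediate early and stress genes (median -0.33) were lower as sets with camera (adjusted p = 5.2e-05, 0.0141 and 0.0115). None passed, with adjusted p = 0.648, 0.835 and 0.769 with an estimated correlation. Major urinary proteins (median 0.41), mitochondrially encoded genes (median 0.11), fatty acid oxidation genes (median 0.10) and female-biased liver genes (median 0.057) were higher (camera adjusted p = 0.000744, 0.00208, 0.0141 and 0.0332). None passed, with adjusted p = 0.769, 0.648, 0.769 and 0.769 with an estimated correlation.

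Female liver gave 13 calls among 12105 genes (7 higher and 6 lower; edgeR). All lay within the 374 t region genes (3.48%; Fisher's exact test, two-sided, p = 1.91e-20). Among the 11731 genes outside it edgeR called 0, with 725 at an unadjusted p under 0.05, and DESeq2 called 15. DESeq2 called 37 genes in all. By edgeR, 8 and 7 were left without pair 1 or 4, and 1 gene outside the region was called without pair 5, without pair 7 or without the pair block. In that last fit H2-Eb1 and H2-Bl did not pass (edgeR adjusted p = 0.5 and 0.425). In the t region, 3 genes rose and 5 fell in the livers of both sexes (0.134 and 0.163 expected; Fisher's exact test, adjusted p = 0.000438 and 2.81e-07).

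Across the 26 liver libraries, the test of a difference between the sexes called no gene by edgeR among 12451 (592 had an unadjusted p under 0.05) and 1 by DESeq2. The endothelial receptor genes Flt4 and Kdr and the mannose receptor gene Mrc1 had the smallest p-values, with male minus female differences of 0.76 ± 0.12, 0.59 ± 0.11 and 0.49 ± 0.11 (edgeR adjusted p = 0.115, 0.504 and 0.720).

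In ovary, 1520401A03Rik rose the most in the t region (5.47 ± 0.43; 0.136 ± 0.108 CPM in +/+ and 7.05 ± 6.5 in +/t, SD, n = 7), a low-count gene whose +/t values spread widely. Of the called t region genes with a mean log2 CPM of at least 1, it was followed by Rnf151 (2.59 ± 0.33), Rsph3a (1.90 ± 0.21), Znrd1 (1.15 ± 0.07) and Znrd1as (0.96 ± 0.13). Jmjd8 (-0.62 ± 0.09), Decr2, an enzyme gene of peroxisomal fatty acid oxidation (-0.57 ± 0.07), and Tulp4 (-0.49 ± 0.07) fell. Outside the region Hmga1b (1.74 ± 0.24) and Rnpepl1 (1.34 ± 0.09; 73.1 ± 9.20 CPM in +/+ and 185 ± 14.4 in +/t) rose and Mfsd4b2 fell (-1.49 ± 0.20). In the t region, Dynlt1c (0.83 ± 0.12) and Rps2 (0.52 ± 0.06) also rose.

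Of 22 t complex named genes in ovary, 3 rose (7 rose and 5 fell adjusted over the list alone). None of the 4 tested distorter and responder genes passed: Tagap1 stood at -0.52 ± 0.09 (edgeR adjusted p = 0.180, lower in 7 of 7 pairs), Fgd2 at 0.16 ± 0.17, Nme3 at -0.053 ± 0.10 and Tiam2 at 0.17 ± 0.08 (1 fell adjusted over the list alone). Immediate early and stress genes (median 0.53), MHC class I genes (median 0.29) and mitochondrially encoded genes (median 0.095) were higher as sets with camera (adjusted p = 6.16e-08, 0.00774 and 0.00893). Each had an adjusted p = 0.921 with an estimated correlation. Of 14 MHC class I genes, 6 rose and 2 fell adjusted over the list alone. Markers of oocytes, granulosa cells, luteal and theca steroidogenesis and oviduct had medians of -0.074, -0.053, -0.072 and -0.019, and none of these lists was called.

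Ovary gave 16 calls among 15324 genes (12 higher and 4 lower; edgeR). They were 13 of the 450 t region genes (2.89%) and 3 of the 14874 others (Fisher's exact test, two-sided, p = 5.26e-18). The biological coefficient of variation was 19.6%, against 6.48% in testis, and DESeq2 called 46 genes (9 outside). Without pair 1, 3, 4, 6 or 8, edgeR called 4, 7, 7, 3 and 3 genes. Outside the region 1 gene was left without pair 1, 2, 5, 6 or 8, pair 5 being that of the even-count library. Without the pair block Amdhd2 passed (edgeR adjusted p = 0.0323), and Rps2 (0.216) and the mitochondrial set (camera adjusted p = 0.138) did not.

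In testis, Gm15821, a noncoding gene within Tap2, rose by 6.52 ± 0.26 (0.118 ± 0.101 CPM in +/+ and 11.6 ± 0.812 in +/t, SD, n = 6). The organic cation transporter gene Slc22a3 rose by 5.69 ± 0.19 (0.277 ± 0.212 and 14.4 ± 4.77 CPM) and Dynlt1c by 3.63 ± 0.06 (9.99 ± 0.656 and 124 ± 12.7 CPM). Znrd1as rose by 3.25 ± 0.04 (91.6 ± 6.88 and 869 ± 56.3 CPM) and the chemokine receptor gene Ccr6 by 1.73 ± 0.13. Olfr112 (-1.17 ± 0.12), Ubash3a (-1.0 ± 0.13), Ttll2 (-0.95 ± 0.06), the receptor gene Mas1 (-0.86 ± 0.04) and Rsph1 (-0.84 ± 0.02; 1649 ± 111 and 920 ± 52.7 CPM) were the lowest of the called t region genes with a mean log2 CPM of at least 1. Outside it, Ppp1cb, which encodes a catalytic subunit of protein phosphatase 1, rose by 1.81 ± 0.05 (76.2 ± 5.52 and 267 ± 16.8 CPM). Hmga1b rose by 1.59 ± 0.16, the testis phosphoglycerate kinase gene Pgk2 by 1.10 ± 0.08, Vstm2a by 0.89 ± 0.14 and Oxgr1 by 0.71 ± 0.14. Gif, the intrinsic factor gene (-1.18 ± 0.18), the collagen gene Col2a1 (-1.07 ± 0.13; 43.0 ± 11 and 20.5 ± 4.09 CPM), Gm7347 (-0.87 ± 0.18), Cpa6 (-0.61 ± 0.14) and Mgst2 (-0.57 ± 0.11) fell.

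Ppp1cb (ENSMUSG00000014956) lies at 32458843 to 32517433 of chromosome 5 in GRCm38, Dynlt1c (ENSMUSG00000000579) at 6601671 to 6609774 and Znrd1as (ENSMUSG00000036214) at 36958592 to 36965625 of chromosome 17. Pgk2 (ENSMUSG00000031233), at 40207015 to 40208640 of chromosome 17, falls just past the 40 Mb boundary. Several of these values are uncertain. Dynlt1c shares near-identical sequence with Dynlt1a, Dynlt1b and Dynlt1f. Gm15821 lies antisense to Tap2, and Slc22a3 overlaps Plg on the opposite strand. Ttll2 and Gm7347 have copies at over 97% identity, and Ppp1cb overlaps Gm43312 on the same strand.

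Of 25 t complex named genes in testis, 2 rose and 7 fell (5 and 10 adjusted over the list alone), Dynlt1a (-0.80 ± 0.04) and Dynlt1f (-0.83 ± 0.04) among the latter. The set was lower with camera (adjusted p = 0.00195; adjusted p = 0.214 with an estimated correlation). Fgd2 fell (-0.61 ± 0.10) among 6 tested genes of the distorter and responder list (2 fell adjusted over the list alone). Tagap1 (-0.95 ± 0.19, edgeR adjusted p = 0.106, lower in 6 of 6 pairs), Nme3 (0.18 ± 0.15), Tiam2 (-0.070 ± 0.17), Smok2a (-0.40 ± 0.63) and Smok2b (-1.06 ± 0.77) did not pass. Smok2a and Smok2b are Smok kinase genes of that list, and neither is known as the responder itself. Of 10 genes of MHC class II and antigen processing, all in the t region, 3 rose (3 rose and 1 fell adjusted over the list alone), including the peptide transporter genes Tap1 (1.29 ± 0.19) and Tap2 (0.68 ± 0.15). Both counts are low, and they are uncertain because Gm15821 matches Tap1 at 97.8% over 134 bases and overlaps Tap2 on the opposite strand by 533 bases. The set of MHC class II and antigen processing, which holds both, was higher with camera (adjusted p = 0.0357; adjusted p = 0.396 with an estimated correlation). Of 19 elongating spermatid markers, 6 rose (12 adjusted over the list alone), by little except for Pgk2. Examples were Cabs1 by 0.11 ± 0.02, Odf1 by 0.096 ± 0.02 and Odf2 by 0.094 ± 0.02. The set was higher with camera (adjusted p = 1.75e-06; adjusted p = 0.246 with an estimated correlation). With pairs 2 and 3 left out, whose +/t libraries are even-count libraries, edgeR called 0 of these 19 markers. Fewer pairs alone make calls less likely, so this does not show that the rises were gone.

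Round spermatid markers (median 0.047) were higher and Leydig cell markers (median -0.25) lower as sets in testis with camera (adjusted p = 0.0463 and 0.000513). None passed, with adjusted p = 0.246 and 0.424 with an estimated correlation. Of 20 spermatocyte markers, Syce2 rose (0.12 ± 0.03) and Msh5 fell (-0.55 ± 0.10), with 1 rise and 2 falls adjusted over the list alone. Of 34 sperm flagellum and motility genes, Tekt4 rose (0.21 ± 0.03), with 2 rises adjusted over the list alone. Rps2 (0.23 ± 0.04) rose among 25 ribosomal protein genes and the heat shock gene Hspa1b (-0.70 ± 0.09), near-identical to Hspa1a, fell among 18 immediate early and stress genes. Adjusted over either list alone the counts were the same. Msh5, Tekt4, Rps2 and Hspa1b all lie in the t region.

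Testis gave 245 calls among 15509 genes (165 higher and 80 lower; edgeR). They were 88 of the 452 t region genes (19.5%) and 157 of the 15057 others (1.04%; Fisher's exact test, two-sided, p = 4.25e-73). The median absolute log2 fold change of the calls was 0.50 inside the region and 0.19 outside it, where 124 rose and 33 fell. Without the pair block 77 genes were called (18 outside). Gm7347, Cpa6, Mgst2, Fgd2, Tap2, Rps2, Syce2, Cabs1, Odf1, Odf2 and Tekt4 (edgeR adjusted p = 0.0552 to 0.925) and the round spermatid set (camera adjusted p = 0.149) did not pass. Without pair 3, 4, 6 or 7 there were 134, 147, 140 and 150 calls (68, 74, 69 and 74 outside). Without both pairs 2 and 3 there were 81 (30 outside, where 19 rose and 11 fell, 25 of them among the 157).

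**Figure D3:**
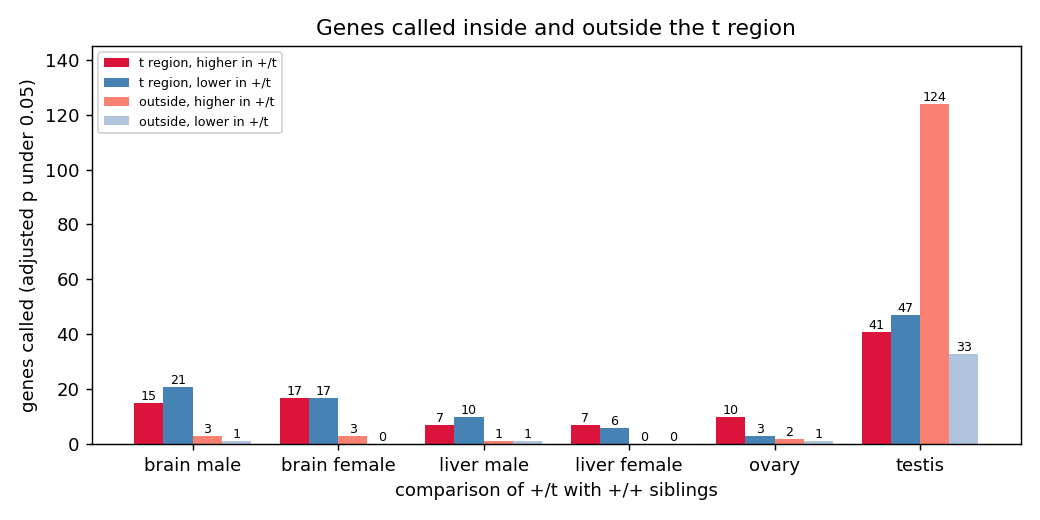
Number of genes called (adjusted p under 0.05) in each comparison of +/t with +/+ siblings, split by location and direction. Testis shows 41 rises and 47 falls in the t region and 124 rises and 33 falls outside it.

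The difference between testis and ovary was tested in all 26 gonad libraries, in which tissue and sex cannot be separated. Dynlt1c differed by 2.80 ± 0.13 (3.63 ± 0.06 in testis and 0.83 ± 0.12 in ovary; edgeR adjusted p = 1.40e-08). Znrd1as differed by 2.30 ± 0.12 (3.25 ± 0.04 and 0.96 ± 0.13; adjusted p = 2.82e-08) and Ppp1cb by 1.83 ± 0.10 (1.81 ± 0.05 and -0.0070; adjusted p = 2.99e-08). Among 17629 genes, 16 were called by edgeR, 12 of them in the t region, with 10 effects higher and 6 lower in testis. Of all tested, 882 had an unadjusted p under 0.05 and DESeq2 called 36. Without female pair 2 there were 25 calls, and without male pair 2, 3 or 6 there were 10 each.

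**Figure D4:**
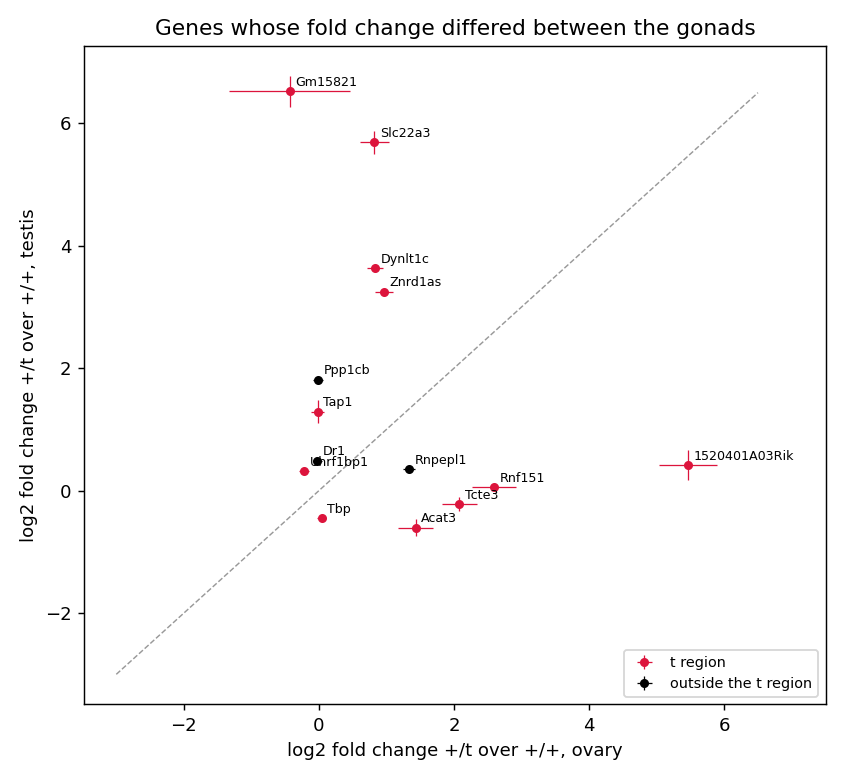
Log2 fold change of +/t over +/+ in testis (y axis) against ovary (x axis) for called genes of the gonad test that were tested in both, with SE bars; the dashed line marks equal change. Dynlt1c, Znrd1as and Ppp1cb lie above the line, and 1520401A03Rik and Rnf151 lie below it.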

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

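Chosen only after the results were seen were the splits for the t region alone, the tests of halved counts, of late spermatids, of sequences like Hmga1b, of reads moved from Hmga1, of a further copy of Rnpepl1, and of lost reads for rises and for falls beyond 2-fold, and the removals of pairs that keep both even-count pairs.

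Outside the t region, 157 genes were called in testis, and 30 when pairs 2 and 3, with even-count +/t libraries, were left out. Halving the counts of these libraries left 156 calls, which decides nothing, since the scaling of libraries takes up such a factor. Among the other 14 removals of 2 pairs (21 to 114 calls, median 46), 3 left as few or fewer, which had been set beforehand as a sign against these libraries. But each of the 3 also left out pair 3, so that sign was wrongly chosen. The 6 removals that keep both pairs 2 and 3 left 34 to 84 calls, none as few as 30, but pair 3 may matter for a reason other than its counts, and the loss of pairs cannot be told apart from an effect of the libraries. A larger share of late spermatids would raise all their markers by about the change seen, but the median of the 19 elongating spermatid markers was 0.0809 (quartiles 0.0476 to 0.0950), against a median rise of 0.16 among the genes called outside the region, a value raised by the choice of called genes. Since those genes were selected for passing as rises, the comparison cannot decide whether that share was the whole cause. With 17 of the 19 markers above 0, a shift of cell shares stays open as the whole cause or a part of it. An effect of the haplotype on genes elsewhere in the genome also stays open, as does a part played by pair 3. Left out alone, pair 2 left 108 calls outside the region and pair 3 left 68. Pairs 1, 4, 6 and 7 left 144, 74, 69 and 74 when left out alone. Pair 3 thus stood close to pairs 4, 6 and 7, which hold no even-count library in testis.

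Rnpepl1, Hmga1b and Gm12355 lie outside the t region and rose in several comparisons. No t region gene resembles Rnpepl1 in sequence (0 found), which argues against reads of an annotated t region gene, and a further copy that goes with the t haplotype and regulation cannot be told apart. Its rise in 100% of 38 tissue samples of sibling pairs decides nothing, because the gene was chosen for such rises. Hmga1b resembles 2 t region genes and Gm12355 resembles 1, Srsf3, so reads from t alleles of those genes may be counted at Hmga1b and Gm12355. Counts passed from Hmga1 to Hmga1b would leave the sum of the 2 genes as it was. The sum changed by 0.72 ± 0.22 in ovary and 0.55 ± 0.07 in testis, which argues only against such passed counts as the whole cause there. It changed by -0.14 ± 0.07 in male and 0.024 ± 0.06 in female brain. In male and female liver, where Hmga1b was not called, it changed by -0.38 ± 0.08 and 0.18 ± 0.10. How reads that match both genes were counted is not given in the sources used here, so the sums do not decide whether such reads play a part.

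In the t region calls went both ways. Reads of t alleles that do not align to the reference could lower counts but not raise them, and 41 genes rose in testis, which argues against this for the rises. For falls, a complete loss would give at most 2-fold if the other alleles of the siblings counted alike. Of 14 called falls beyond 2-fold in the 6 comparisons, 4 exceeded it by more than 2 SE, and 2 of these had a mean log2 CPM of at least 1: H2-Q1 in male brain (-3.02 ± 0.28) and H2-Eb1 in female liver (-1.44 ± 0.12). This argues against loss of t reads alone for these 2 in those comparisons, while differences between the other alleles of the siblings were not tested. In male liver H2-Eb1 stood at -1.02 ± 0.16, a fall that loss alone would allow. Of the 41 falls within 2-fold also tested in male brain, 56.1% stood higher there by more than 2 SE (median log2 fold change -0.49 in testis and -0.10 in male brain). This share is raised by the choice of genes called as falls in testis, to a degree that was not tested, and the tissues may use different exons. The share therefore argues only weakly against loss alone for that part. Lost reads for the other falls, and differences in the activity of the t alleles, stay open.

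Other splits of the libraries were fitted for each count. For genes called in the t region, 1 of 100 splits was as large in each of the 6 comparisons, the real one. It gave 36 in male brain (highest other 7), 34 in female brain (6), 17 in male liver (1), 13 in female liver (1), 13 in ovary (1) and 88 in testis (1). Between 3 and 14 of the 100 splits, the real one included, part every pair. The others rest on fewer pairs, so these shares alone do not exclude chance. For all genes called, few splits were as large in female brain (37; 3 of 100 as large, highest other 303), male liver (19; 1, 13), female liver (13; 1, 6), ovary (16; 2, 26) and testis (245; 1, 12). These shares were not adjusted over the counts tested. In female brain and ovary other splits gave more calls than the real one, so these splits do not exclude chance there. In male liver, female liver and testis the real split alone was as large, which argues against chance. Male brain stays undecided by these splits (40; 7 of 100, 252). With pair blocks a pair that is not parted adds nothing to the genotype term, and 5 of the 7 part 1 pair alone. These 5 part the same pair and gave the same 252 calls, so they are 1 fit drawn 5 times. The 100 splits are thus not 100 separate fits, and the share of 7 of 100 decides nothing. Why some splits of male and female brain gave 252 and 303 calls was not tested. The 252 calls came from splits that part only pair 5, as did 5 of the 7 splits as large in male brain, and the 303 from a split that parts pairs 4, 5 and 7, while the real split parts every pair.

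Outside the t region chance can be excluded in testis (157; 1 of 100 as large, highest other 11), where the splits that part every pair, given below, gave the same answer. In ovary 3 of 100 were as large as the count of 3 (highest other 25), a share under 0.05 that was not adjusted over the counts tested. Over these splits chance cannot be excluded in male brain (4; 8, 248), female brain (3; 5, 297) or male liver (2; 8, 12). In female liver the count of 0 (edgeR; 725 at an unadjusted p under 0.05, 15 by DESeq2) makes all 100 splits as large (highest other 5), so the splits test nothing there. For the number of lists called it cannot be excluded in male brain (6; 19 of 100, highest other 8), female brain (6; 50, 11), male liver (4; 70, 11), female liver (7; 50, 12), ovary (3; 89, 13) or testis (5; 6, 5). For sex differences, 2 of 60 exchanges of pairs in the gonads, the real grouping included, were as large as its count of 16 (highest other 17). That share was not adjusted over the counts tested, and the exchanges mix testis with ovary pairs. Chance is thus not excluded there. In brain (0 by edgeR, 815 unadjusted, 1 by DESeq2; 100 of 100, 75) and liver (0 by edgeR, 592 unadjusted, 1 by DESeq2; 100 of 100, 3) a count of 0 leaves nothing for the splits to test.

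Splits that part every pair, as the real one does, were compared as well. For all genes called, the real one alone was as large in female brain (of 64; highest other 13), male liver (of 64; 3), female liver (of 32; 6) and testis (of 32; 1), and 2 of 64 were in ovary (22). T region calls are a part of all calls, so no other such split reached the real t region count in the first 4. Nor did one in ovary, where all 22 calls of the other split lay outside the region. This argues against chance for the t region calls of these comparisons. The 16 such splits of male brain are too few for a share under 0.05 (real 40, highest other 5; outside the t region 4 and 4). Outside the t region, 2 of 64 were as large in female brain (real 3, highest other 12), male liver (2; 3) and ovary (3; 22), and 1 of 32 in testis (157; 1). Among splits that part every pair, the share as large was thus under 0.05 for these 4 counts. Over all splits it was not in female brain and male liver, so chance is not excluded for their counts of 3 and 2 genes. In ovary another split gave 22 calls against 3, and the shares were not adjusted over the counts tested. For lists chance cannot be excluded in female brain (29 of 64 as large), male liver (46 of 64), female liver (19 of 32), ovary (60 of 64) or testis (3 of 32).

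The tests of testis against ovary called 16 genes, with differences of 2.80 for Dynlt1c, 2.30 for Znrd1as and 1.83 for Ppp1cb. A sibling pair lay far from the others of its group in 13 cases of a named gene in a comparison (11 genes; 8.97% of the cases tested), and chance alone puts about 1 in 20 groups there. Tagap1 fell further in pair 2 than in the others in male brain (-1.91 against -1.10 to -0.82), female brain (-1.75 against -1.04 to -0.52) and testis (-1.97 against -0.98 to -0.42), and the male and female pairs 2 come from the same litter. Pair 2 also stood apart for H2-Q1 in male brain (-1.32 against -3.69 to -3.23), Nme3 in male liver (-0.21 against 0.00467 to 0.14), and Rps2 (0.10 against 0.23 to 0.30) and Smok2a (6.28 against -1.98 to 0.80) in testis. Pair 5 stood apart for Prr18 (0.68 against 0.31 to 0.38) and Rsph1 (-1.12 against -1.01 to -0.98) in male brain and Tulp4 in female brain (-0.11 against -0.44 to -0.39). In testis, pair 1 stood apart for Tap2 (1.39 against 0.41 to 0.65) and Cpa6 (-0.033 against -0.85 to -0.57), and pair 4 for Mas1 (-0.67 against -0.93 to -0.85).

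Total counts in M (mega) were far from the group in 6 of 12 groups: brain male +/+ of pair 3 (45.2 against 18.8 to 22.4), brain female +/+ of pair 4 (42.0 against 19.1 to 26.7) and brain female +/t of pair 6 (41.2 against 17 to 24.6). The others were liver male +/t of pair 4 (21.2 against 9.43 to 13.3), ovary +/t of pair 5 (23.9 against 11.8 to 15.4) and liver female +/+ of pair 4 (14.8 against 11.4 to 12.7). All but the last are even-count libraries.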

How the results depend on the processing

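Halving the counts of even-count libraries and leaving out pairs that hold one were tests chosen only after the results were seen. On simulated data edgeR called 50% of 1.5-fold changes in ovary and 88.0% in male brain, which differ in depth as well as in variation. Exchanging 1 pair of labels in male liver, or leaving out 1 pair in any of the 6 comparisons (in male brain for calls outside the t region only) or in the tests of sex differences, moved at least 1 count by over 1.5 times. Relative log expression factors changed no count by that much. Halved counts did not either, but the scaling of libraries takes up such a factor. Over all alternatives, 151 counts of genes kept within 1.5 times, 31 rose and 66 fell by more. Of single genes, 1703 results kept direction and side of the threshold, 318 lost the call, 18 gained it and 3 reversed. Of lists, 324 kept it, 40 lost it and 1 gained it. Unless the setting itself leaves out genes or samples, the cause was not tested.

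With DESeq2, 52 genes were called in male liver (13 outside the t region), 37 in female liver (15), 46 in ovary (9), 9 outside in male brain and 8 outside in female brain. For sex differences it called 1 in brain, 1 in liver and 36 in gonads. With no filter, 82 were called in male brain (40 outside), 77 in male liver (43), 28 in female liver (7), 9 outside in female brain and 13 for the sex difference in brain. A minimum count of 50 gave 1 outside in male brain and 10 in ovary (1 outside). With the boundary at 35 Mb, 9, 6, 6, 4 and 6 calls lay outside in male brain, female brain, male liver, female liver and ovary. Exchanged labels in male liver pair 3 gave 0 and 0 outside by edgeR.

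Without the replicate block, 19 genes were called in male brain, 21 in female brain and 77 in testis (18 outside), 1 outside in male liver, 1 outside in female liver, and 3 lists in male brain; of the calls with the block, 18 of 40, 21 of 37 and 76 of 245 were kept in male brain, female brain and testis. The report gives those named genes and lists whose call changed. With even-count pairs left out, 2 were called outside in male brain, 12 in female brain, 8 in male liver (1 outside), 1 outside in ovary, 81 in testis (30 outside) and 1 for the sex difference in brain. With an estimated correlation 0 lists were called by camera in all 6 comparisons, and without t region genes 2 were in testis.

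With each pair left out in turn, 29 to 39 genes were called in male brain (2 to 6 outside), 23 to 33 in female brain (2 to 4), 6 to 12 in male liver (0 to 1), 7 to 11 in female liver (0 to 1), 3 to 16 in ovary (1 to 2) and 134 to 227 in testis (68 to 144). For sex differences there were 0 to 2 in brain (2 without female pair 6), 0 to 1 in liver (1 without female pair 1) and 10 to 25 in gonads. Signs turned for uncalled genes only: Fgd2 in male brain without pair 1 (-0.032; range -0.032 to 0.18 with a pair left out) and Tiam2 in testis without pair 2 (0.016; range -0.16 to 0.016) and with even-count pairs left out (0.11).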

Other observations

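The tests of liver lists by sex were chosen only after the results were seen, and the set of X chromosome genes was not planned.

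Genes named in this paragraph and the next were chosen after their values were seen. In testis, Ppp1r2, which encodes an inhibitor of protein phosphatase 1, rose by 0.39 ± 0.04 (edgeR adjusted p = 6.91e-06), beside the rise of Ppp1cb, a catalytic subunit of the same enzyme. Dr1, a repressor of transcription, rose by 0.49 ± 0.03 (edgeR adjusted p = 7.93e-08), and Igfbp7, an insulin-like growth factor binding protein gene, fell (-0.47 ± 0.05; edgeR adjusted p = 1.61e-05). None of these 3 genes passed in brain, liver or ovary, where Ppp1r2 stood at -0.048 to 0.053, Dr1 at -0.030 to 0.056 and Igfbp7 at -0.15 to 0.14. Between testis and ovary the difference was tested for each, and it passed for Dr1 alone (0.52); between testis and the other tissues it was not tested.

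Tcte3, a dynein light chain gene of the t complex known from testis, rose in male brain (4.01 ± 0.46), female brain (3.07 ± 0.28) and ovary (2.08 ± 0.26) from very low counts and stood at -0.22 ± 0.11 in testis. Its counts are uncertain, since it matches Gm3417 at 98.8% and overlaps Gm3448 on the same strand. 1520401A03Rik rose in male brain (4.79 ± 0.33) and female brain (6.34 ± 0.33), as it did in ovary, also from very low counts. H2-Ob, of MHC class II, rose in testis (4.39 ± 0.44) and did not pass elsewhere.

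As sets of genes by location, the t region had no common direction in any comparison (camera adjusted p = 0.117 to 0.912; 0.124 to 0.926 with an estimated correlation), while a test for changes in either direction gave p = 2.48e-07 or less in each (fry). X chromosome genes were lower in testis (unadjusted camera p = 0.00916; 0.118 with an estimated correlation) and female liver (0.0293; 0.162) and higher in male brain (0.0413; 0.397). In the other 3 comparisons the p was 0.227 to 0.816.

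As sets, endothelial markers were higher in +/t male liver and lower in +/t female liver with camera, but in neither with an estimated correlation (adjusted p = 0.747 and 0.648). The hypothesis that such differences depend on sex was tested by an exact permutation of the 13 pairs between the sexes for all 22 lists tested in both livers (1716 regroupings). None of the 22 passed. For endothelial markers the mean difference was 0.10 in males (higher in 5 of 7 pairs) and -0.22 in females (higher in 2 of 6), with an exact adjusted p = 0.218. For major urinary proteins (-0.30 and 0.32; higher in 1 of 7 and 4 of 6 pairs) it was 0.429, and for macrophage markers (-0.081 and -0.17; 2 of 7 and 2 of 6) 0.94. The permutation treats the pairs as exchangeable, although some male and female pairs come from the same litter. The exchange of labels in male liver pair 3 was not applied to this test.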
